A study of Mus musculus with 18 samples.

How the data were processed

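Chromatin accessibility was profiled by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open DNA, in naive CD4 T cells of C57BL6/J mice. Per the labels, 500000 cells per library were lysed for 15 min and tagmented for 30 min at 37 °C. The cells were sorted by the level of a destabilised GFP reporter of Nr4a1, a gene switched on by T cell receptor (TCR) signals, into low and high fractions of tonic TCR stimulation. Both fractions came from the spleen, the mesenteric lymph nodes and the axillary lymph nodes, with 3 biological replicates each, so that 18 libraries formed 6 groups. Groups and replicate numbers were taken from the sample titles. The titles do not say which replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

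The deposited data are 1 peak list per library on mouse build mm10, so these peaks were called per sample. Whether peaks were also called on pooled samples is not given in the sources used here. Per the submitters' processing notes, the tools were Trimmomatic 0.33, Bowtie2, bedtools and MACS, and the versions of the last 3 are not given in the sources used here. Duplicate handling, read shifting and caller options are not given in the sources used here either. Each deposited peak has a position, a summit, a score, a fold enrichment (the ratio of summit reads to the caller's local background), a −log10 p and a −log10 q. These peak values are the authors' own and were used to describe, rank and filter peaks within a list. The deposited score equalled the integer part of 10 times the −log10 p in 314754 peaks and differed in 75. The smallest deposited −log10 p was 5.001.

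Of 314829 peaks, 314425 on chromosomes 1 to 19 and X were used and 404 on other sequences were set aside. Peaks of all libraries were merged into 33115 union regions with a median width of 425 bp, and a library was counted as having a region when a peak of it overlapped the region by at least 1 bp. Genes came from an annotation table of the same build (GRCm38.p6) with 21631 protein-coding genes, which gives gene starts and ends. The strand of genes was not used here, so the distance to a transcription start site, which had been planned, was replaced by the distance to the nearer end of a gene. A region was assigned to the protein-coding gene with the nearest end within 100000 bp of its centre in list tests (92.5% of regions), and named by the nearest gene without a limit. Regions are described only as inside or outside a gene. No genome sequence was used, so the planned motif searches and GC matching were not run.

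Sequencing depth was recovered from the peak values. The caller's fold is (pileup + 1)/(background + 1) and its p is a Poisson tail, and exactly 1 pair of whole-number pileup and background matched both values within 0.002 in 99.3% of peaks. Local backgrounds, multiplied back to a 10000 bp window, were whole reads within 0.02 in 100% of these peaks. The smallest background of a library is its genome-wide average, given below as reads per 10 kb, which is a relative depth and not the number of reads sequenced. The narrowest peak of a library equals the caller's fragment estimate. For a comparison at equal depth, pileups and local reads were thinned binomially to the depth of the shallowest library (20 draws) and peaks were kept at a −log10 p of at least 5. Peak numbers are the mean of the draws, and presence of regions and shares near gene ends come from the first draw. This choice, and every use of recovered reads, was made after the data were examined.

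Values per library were compared between high and low by an exact permutation test within organs (8000 relabellings, smallest p 0.00025), and between organs by an exact permutation test within reporter levels (400 relabellings, smallest p 0.005). In a single organ, 3 against 3 libraries cannot give a p below 0.1 by these exact tests. Each union region present in 6 to 12 libraries was tested for high against low with Fisher's exact test (9 against 9, smallest p 4.11e-05). Each region present in 5 to 13 libraries was tested across the 3 organs with the exact Fisher-Freeman-Halton test. Tests were two-sided except those of library similarity, which used the Jaccard index of region sets and were one-sided. Benjamini-Hochberg adjustment at 0.05 ran over all regions tested, over lists, or over the 3 pairs of organs. Within an organ, regions with a peak in 3 of 3 libraries of a level and 0 of 3 of the other were counted, beside the same count in the other 9 splits of the 6 libraries. The tests, the alternatives, 11 gene lists and 7 lists of markers of other cell types were fixed before the data were examined. Mx1, Mx2 and Ighm had no entry in the annotation table.

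Genes were named in the text by a rule fixed at the same time. It takes, for high against low, the 12 regions per direction with the smallest p, ordered by the difference in libraries and then by the mean rank percentile of their peaks, each with another nearest gene. Between organs it takes 8 regions per organ, and within each organ 5 per direction. It adds members of the lists whose region was called, up to 4 per list, and Nr4a1 and Cd5 in every library. Names outside it were chosen after their values were seen.

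Reads in the 10 kb around a summit, recovered as above, were compared at 8428 regions with a value in all 18 libraries, as log2(reads + 1) after scaling to the library total outside the region of high background around Nr4a1. The test was an exact permutation test per region with 8000 relabellings and Benjamini-Hochberg adjustment, and standard errors came from 12 residual degrees of freedom.

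The recovery of pileups, both tests of presence per region, the test of recovered reads per region and the comparison of the high against low difference between organs were tested on simulated data, and the other tests were not. Of 15538 simulated peaks, 99.9% gave back the right pileup. In simulated presence tables of 33115 regions, the high against low test called 79.5% of 200 regions changed from 5% to 95% of libraries, with 1 unchanged region called, and 25% of 200 changed from 15% to 85%, with 2 unchanged regions called. The test across organs called 39% and 0% of these. In simulated reads of 8428 regions, the test of recovered reads called 96% of 200 regions with a fold of 1.5 and 26.5% with a fold of 1.25, with 10 and 4 unchanged regions called, and 0 regions where none was changed. In 1000 simulated sets of library values with an organ effect of 20, a level effect of 5 and an interaction of 10 or 0 times the SD, the planned comparison of the high against low difference between organs passed in 0% with and 0% without the interaction. With organ and level means removed it passed in 100% and 4.2%. Alternatives were a stricter −log10 p of at least 10, equal list lengths (the 14372 strongest peaks of every library), a peak covering at least 50% of a region, 500 bp windows, no filter on regions, stratified and blocked tests, covered length, wider gene-end and narrower gene windows, and leaving out each library. Added after the data were examined were thinning, 1 value per group, the short-fragment libraries alone, the comparison of the high against low difference between organs with organ and level means removed, and tests without mesenteric libraries or without chromosome 14. Counts were also set beside those of 100 splits of the libraries drawn with seed 1 and balanced within organs or levels, the real split among them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.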

Results

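Peak lists of 18 ATAC-seq libraries described open chromatin in naive CD4 T cells sorted for low or high Nr4a1 reporter signal from spleen, mesenteric and axillary lymph nodes, with 3 libraries per group. The series asks how tonic TCR stimulation and the organ of residence relate to the chromatin of these cells. The lists held 14372 to 23129 peaks each on chromosomes 1 to 19 and X, and 8756 of 33115 union regions were present in all 18 libraries, while 6294 were present in 1. Recovered depth was lowest in axillary low libraries (9.08 ± 0.541 reads per 10 kb, SD, n = 3) and highest in mesenteric high libraries (16.6 ± 0.0549, n = 3). Libraries of the same group differed by no more than counting noise, with a chi-square per shared summit of 0.817 to 0.901 in 18 pairs, against 1.09 to 1.84 in 135 pairs of different groups. The labels call these libraries biological replicates, so each was kept as a replicate. As no variation beyond counting noise was seen within groups, p-values and standard errors below may measure technical spread between 6 preparations only.

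High against low reporter cells were compared first, which addresses what accompanies stronger tonic TCR signals. A region outside the gene Serp2 (chr14:76764403-76764915, 207585 bp from its nearer end) and a region next to Crb2 (chr2:37765032-37765478) had a peak in 9 of 9 high and 0 of 9 low libraries. A region 35083 bp outside Cd200 (chr16:45346775-45347282), which encodes an inhibitory surface ligand, had a peak in 8 of 9 high and 0 of 9 low libraries, as did a region next to Alkbh3, a DNA repair enzyme. Regions near Magi2, Sbk1, Zmiz1, Pdhx and Cfap73 stood at 9 high against 1 low, and regions near Tnfrsf19, Mllt3 and Slc4a1ap at 9 against 2. In the other direction, a region near Jmjd1c, a histone demethylase gene, had a peak in 0 high and 6 low libraries, and regions near Stt3b, Sntb2 and Slc17a5 in 3 high and 9 low. Regions near Maml2, a Notch coactivator gene, and Fancc stood at 2 against 8 and 1 against 7. The list closed with Irf2, Mc2r, Eef2kmt, Zmat4 and Dse at 3 against 8 and Plat at 1 against 6. The authors' fold enrichment at these 24 regions ran from 5.93 ± 0.911 at Cfap73 to 9.52 ± 2.41 at Tnfrsf19 (SD over the libraries with a peak). It was 6.85 ± 2.02 at Serp2 and 6.75 ± 1.22 at Cd200. The median peak of a library had 7.83 to 8.32. A list of called peaks does not show how open a region without a peak was.

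**Figure D1:**
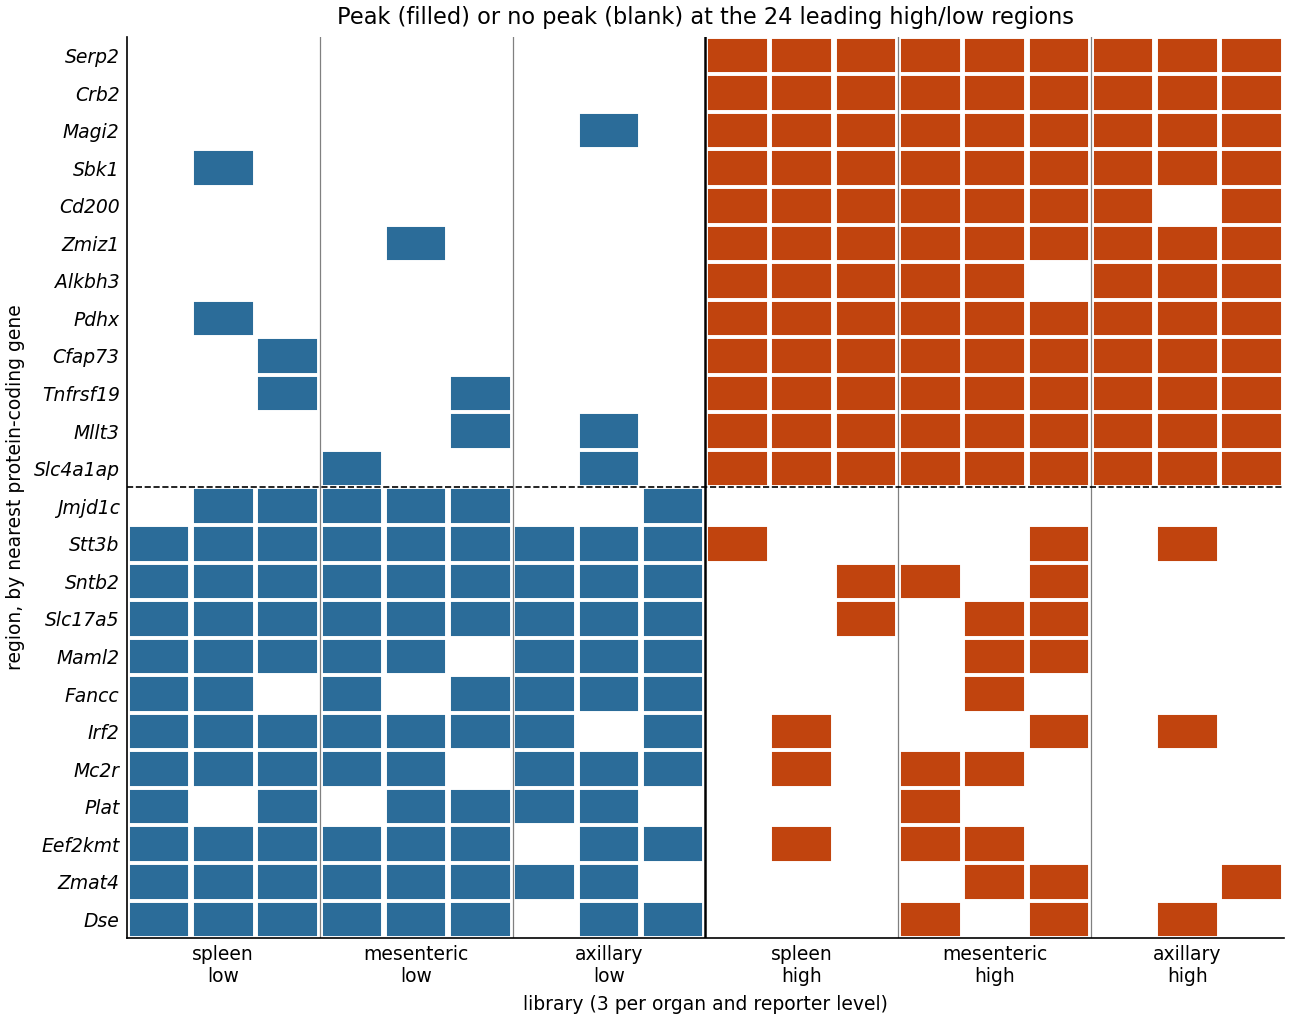
Each row is a region named by its nearest gene, each column a library, and a filled cell marks a peak; the 12 upper regions lead in high libraries and the 12 lower ones in low libraries. The regions near Serp2 and Crb2 are filled in 9 of 9 high and 0 of 9 low libraries.

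None of these regions passed the test over all regions. Of 5737 regions tested with Fisher's exact test, 0 were called after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.118. At an unadjusted two-sided p under 0.05 there were 335 regions more frequent in high and 15 in low libraries. At equal depth the tilt was smaller, with counts of 198 and 30. With the 14372 strongest peaks of every library the counts were 80 and 83. Equal lists balance high and low by construction, so these counts do not show what caused the tilt. Without the mesenteric libraries the counts were 27 and 8, from fewer libraries and so with less power. The regions near Serp2, Zmiz1 and Tnfrsf19 lie on chromosome 14, on which recovered reads were higher in high libraries along much of its length.

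Of 200 regions assigned to the TCR signal and activation list, 38 were tested, and 4 passed an unadjusted p under 0.05. All 4 were more frequent in high libraries, as were 335 of 350 over all regions. These were both regions near Cd200 (8 against 0 and 8 against 3), a region inside Nr4a1 (7 against 0) and a region next to Egr3 (8 against 3), an immediate early transcription factor gene that also lies on chromosome 14. Adjusted over the list alone, the Cd200 region at 8 against 0 and the Nr4a1 region passed (adjusted p = 0.0156 for the smallest, Fisher's exact test), while over all regions tested 0 did. The Nr4a1 region lies in a block of very high local reads, described below, whose copy number is not given. Of 36 tested regions of negative regulators of TCR signal, 4 passed unadjusted, again all more frequent in high libraries. Regions of Dgkz, a diacylglycerol kinase that dampens TCR signals, and near Tnfaip3, an inhibitor of NF-kB, stood at 7 against 0 and passed when adjusted over the list alone (smallest adjusted p = 0.0407, Fisher's exact test), and regions of Ubash3b stood at 6 against 0 and 9 against 3. These 4 calls over the list alone ended at equal list length and at equal depth. At equal list length Cd200, Dgkz and Tnfaip3 stood at 4 against 0 and Nr4a1 at 5 against 0, too few libraries to be tested. At equal depth Cd200 and Tnfaip3 stood at 7 against 0, Nr4a1 at 6 and Dgkz at 5 against 0, and the smallest adjusted p over each list alone was 0.086 and 0.0769 (Fisher's exact test).

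Other lists gave no call in either count. Unadjusted, 5 of 20 tested effector and memory regions (near Gzmb, Itgb1, Il2rb, Cd44 and Cxcr6), 4 of 37 naive and quiescence regions (near Btg1, S1pr1 and Bcl2), 3 of 21 homing and migration regions and 1 of 25 retinoic acid and TGF-beta regions (Pmepa1) were more frequent in high libraries, and 1 of 22 regions of AP-1, NFAT, NF-kB and IRF factors (Irf2) was more frequent in low libraries. The T helper, regulatory T cell, interferon response and housekeeping lists, and the lists of B cell, CD8 T cell, NK cell, myeloid, dendritic, erythroid and stromal markers, had 0 such regions. The marker lists had only 1 to 5 tested regions each and the housekeeping list 2, so their counts of 0 say little. As shares of a library's regions, 17 of 18 lists did not differ between high and low. The TCR signal list took 0.553% ± 0.0248 in high and 0.545% ± 0.029 in low libraries (n = 9 each, exact permutation p = 0.477). The NK cell marker list took 0.0228% ± 0.0043 in high and 0.0264% ± 0.00232 in low libraries (adjusted p = 0.027, exact permutation, n = 9 each), which rests on 6 regions and ended at equal list length (adjusted p = 0.405) and at equal depth (adjusted p = 0.442).

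Nr4a1 itself, the gene the reporter reads, had 7 regions. Of these, 4 were present in all 18 libraries and 1 in 8 of 9 high and 8 of 9 low libraries. A region 3339 bp outside the gene (chr15:101250275-101250852) was present in 9 high and 4 low libraries, and a region inside the gene (chr15:101256069-101256399) in 7 high and 0 low libraries (Fisher's exact p = 0.00226, adjusted p = 0.382). The authors' fold at this inner region was 2.40 ± 0.112, below that of the shared Nr4a1 regions (5.28 ± 0.667 to 9.90 ± 1.71). At the strongest peak of each of the 4 shared regions, fold ran lower in high libraries. High against low values were 7.547 to 8.889 against 10.39 to 12.05 and 4.138 to 4.95 against 5.286 to 7.583. The others were 4.355 to 5.338 against 5.336 to 6.292 and 5.762 to 7.281 against 8 to 10.03. The region outside the gene had 2.689 to 2.977 against 2.237 to 2.774. All 7 Nr4a1 regions lie in a block of 22 regions over 152801 bp (chr15:101210096-101362896) with very high local reads, from 10.4 to 126 times the genome background, against 4.01 times at the median peak. The median of local reads over 11 block regions present in every library was taken per library. It was 64.7 ± 6.78 times background in high and 42.5 ± 1.70 times in low libraries (SD, n = 9 each). The ratio was 1.51 (exact permutation p = 0.00025, the smallest possible). Taken singly and scaled to the library total outside the block, the 11 regions had ratios of 1.497 to 1.995. The copy number of the block is not given, so peaks at Nr4a1 cannot be read as opening of the gene's own locus alone. Cd5, a surface regulator whose level follows TCR signal strength, had 5 regions at 4 against 3, 8 against 6, 1 against 1, 6 against 4 and 7 against 3 libraries, and 0 of those tested passed.

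**Figure D2:**
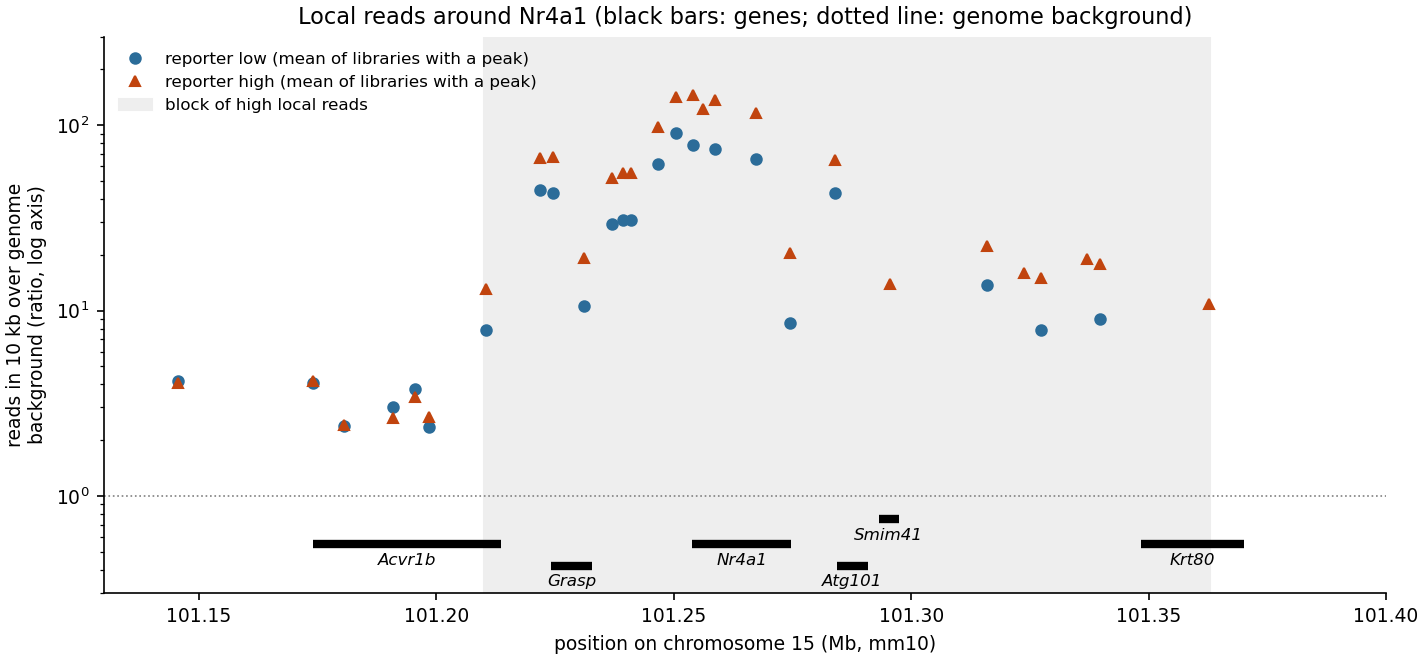
Reads in 10 kb around each region, as a ratio to the genome background on a log axis, along chromosome 15 (Mb); circles are means over low and triangles over high libraries with a peak. Inside the shaded block of 22 regions these means are 7.82 to 146 times background, and in the last region before it 2.35 (low) and 2.67 (high) times.

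High libraries also had more peaks. They held 18711 ± 3401 peaks against 16225 ± 1567 in low libraries (SD, n = 9 each), a difference of 2487 (exact permutation p = 0.00575). The difference was 5697 in mesenteric nodes (23043 ± 137 against 17346 ± 144, n = 3, exact p = 0.1, the smallest 3 against 3 allow), 939 in spleen (exact p = 0.7) and 824 in axillary nodes (exact p = 0.2). Without spleen low replicate 3, the shallowest spleen library, the spleen difference was -152. Depth differed in the same direction, 13.4 against 11.3 reads per 10 kb (exact permutation p = 0.00725), and at equal depth the difference was 1249 peaks (exact permutation p = 0.0065). Libraries fell into 12 with a fragment estimate of 161 to 176 bp and 6 with 216 to 236 bp. Within the short ones the difference over spleen and mesenteric nodes was 2773 (permutation p = 0.075), and within the long ones of the axillary nodes 604 (exact p = 0.3). With 1 value per group, the design allows no p below 0.25. The share of peak summits within 1000 bp of a gene end was lower in high libraries, 44.4% ± 4.09 against 47.5% ± 1.91 (n = 9 each, exact permutation p = 0.0175), and in mesenteric nodes 39.1% ± 0.237 against 46.6% ± 0.186 (n = 3). At equal list length this difference was 0.0317 percentage points in the opposite direction (exact permutation p = 0.883), and within the short-fragment libraries it was -3.37 (permutation p = 0.09).

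**Figure D3:**
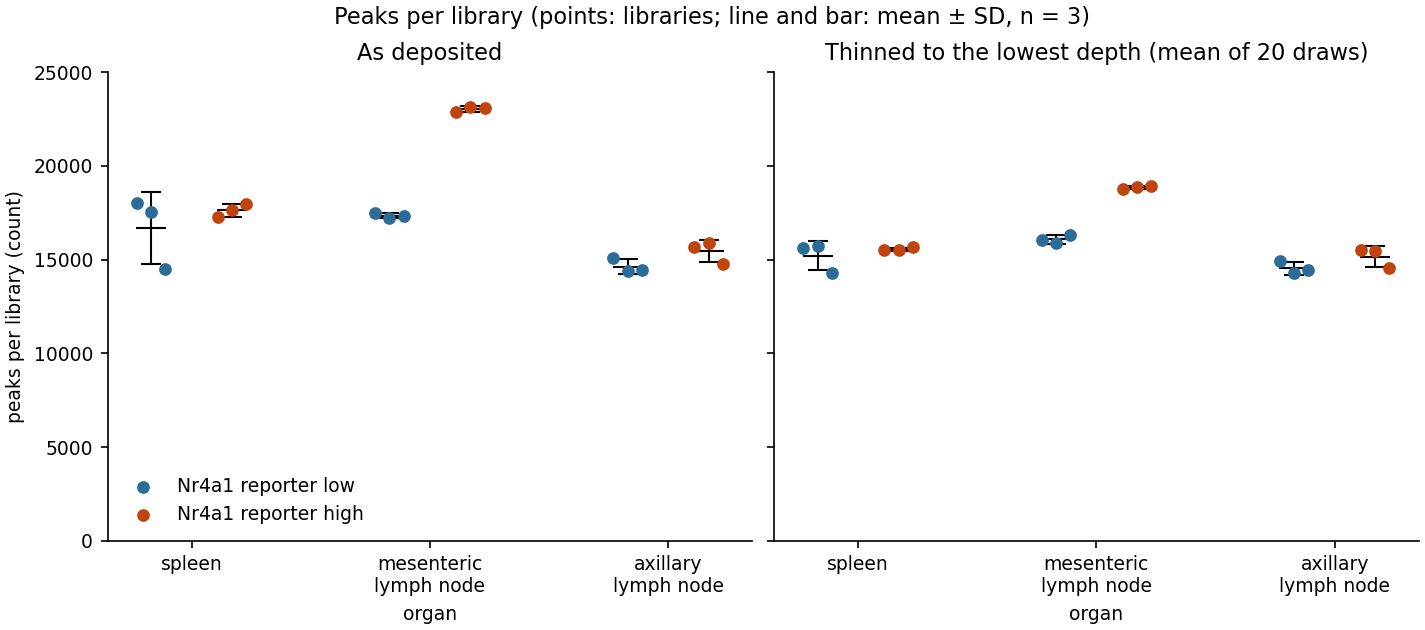
Peaks per library (count) by organ, for low and high libraries, as deposited and after thinning to the lowest depth; points are libraries, and lines with bars are the mean ± SD of 3. The mesenteric high libraries (22885 to 23129 peaks) lie above all others, also after thinning (18795 to 18945).

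Within each organ, regions with a peak in all libraries of a level and none of the other were counted. In spleen, regions near Arid1b, Siah3, Mllt3, Rnf41 and Pard3 led the 205 with a peak in 3 of 3 high and 0 of 3 low libraries, and regions near Ifi206, Trim36, Adipor2, Tcf20 and Cd163 led the 96 in the opposite direction. In mesenteric nodes, regions near Pdcd1, an inhibitory receptor gene induced by TCR signals, Nr4a1, Gbp6, Arl6ip5 and Eps15l1 led 1040 against 18. The 18 were led by Arid1b, Ybx3, Ttll5, Krr1 and a region 110807 bp from Ifng. In axillary nodes, regions near Tnfrsf19, Cdh10, Sit1, which encodes a transmembrane adaptor of T cell signalling, Cr2 and Sbk1 led 188, and regions near Zfp7, Stk4, Deup1, Sema7a and Pigp led 72. With equal list lengths the counts were 107 and 121 in spleen, 170 and 129 in mesenteric and 117 and 113 in axillary nodes. Presence of a region cannot be tested in a single organ, as exact tests of 3 against 3 cannot give a p below 0.1. The highest count in another split of the same 6 libraries, both directions together, was 225 against 301 in spleen, 200 against 1058 in mesenteric and 186 against 260 in axillary nodes.

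Regions that led in high cells were shared between organs more often than independent lists would be. Spleen and mesenteric nodes shared 21 regions (6.44 by independence, Fisher's exact p = 2.27e-06), spleen and axillary nodes 8 (1.16, p = 2.42e-05) and mesenteric and axillary nodes 19 (5.90, p = 8.26e-06). In the low direction 0, 1 and 0 regions were shared. These p-values treat regions as independent and equally likely to vary, although neighbouring regions are linked and weak peaks vary most. Regions with opposite directions in different organs also exceeded independence, at 13 against 6.48, so the excess cannot be read as a shared direction alone. High minus low differences in recovered reads correlated between organs at 0.136 to 0.217 over 8417 regions. The difference in peak number between high and low was compared between organs as spleen minus mesenteric (-4758), mesenteric minus axillary (4873) and spleen minus axillary (115). None of these passed the planned exact permutation test (adjusted p = 0.165, 0.203 and 0.965). Exchanging organ labels also carries the organs' own difference in peak number, so that p could not fall below 0.1 for mesenteric minus axillary nodes. For that pair the planned test decides nothing. For spleen minus mesenteric (unadjusted p = 0.055, exact permutation) it could pass, and it did so without spleen low replicate 3. With organ and level means removed first, an approximate permutation test chosen after the result was seen, both differences to mesenteric nodes passed (adjusted p = 0.0075 each), and spleen minus axillary did not (adjusted p = 0.945). At equal depth the values were -2450 and 2173 (adjusted p = 0.0075 each, permutation) and -277 (adjusted p = 0.605).

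The second question was how the organ of residence relates to chromatin. Regions near Kctd8, Cenpe, a mitotic kinesin gene, and Pttg1ip2 had a peak in 6 of 6 spleen libraries and in 0 of 12 node libraries. A region near Cd69, an early activation gene whose product retains lymphocytes in tissue, stood at 6, 1 and 0 of 6 libraries in spleen, mesenteric and axillary nodes, and Rfx4, Ptgs2, Lmna and Prkag2 completed the spleen list. Regions near Kcna3, the potassium channel Kv1.3 of T cells, Pard3, Fam102a, Zcchc10, Ccdc66 and Tmem159 had a peak in 6 of 6 mesenteric and 0 of 12 other libraries, followed by Hsp90b1 and P4ha2. Axillary nodes led at a Pdhx region (0, 5 and 6 libraries), at Asap1 (0, 3 and 6), at 1700056E22Rik (1, 1 and 6), and at Cs, Rad23b, Upb1, Camk2g and Mms22l. Of 7630 regions tested, 0 were called by the exact Fisher-Freeman-Halton test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0881), and 851 passed unadjusted. Mesenteric nodes had the most libraries with a peak in 591 of these and axillary nodes the fewest in 547, in the order of the depth of the libraries. At equal depth 508 passed, with mesenteric nodes highest in 312 and axillary nodes lowest in 232. At equal list length, which balances the organs by construction, 357 passed. Mesenteric nodes were then highest in 92 and lowest in 84, and axillary nodes highest and lowest in 111 each.

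Adjusted over the list alone, 4 regions of negative regulators of TCR signal changed between organs, at Dgkz and Cblb (2, 6 and 0 libraries in spleen, mesenteric and axillary nodes), Ubash3b (0, 6 and 2) and Socs3 (6, 6 and 1), as did a T helper region at Stat6 (0, 6 and 1), the transducer of interleukin 4 signals. Over all regions tested, 0 of these passed, and at equal list length and at equal depth 0 of the 5 passed over the list alone. In the TCR signal list 8 of 54 tested regions passed unadjusted, among them Icos (0, 5 and 0), Egr1 (0, 5 and 1) and Egr2 (2, 6 and 2), and 0 passed over the list alone. The retinoic acid and TGF-beta list covers pathways active in gut-draining nodes. Its share of regions was 0.323% ± 0.0134 in mesenteric, 0.273% ± 0.0167 in spleen and 0.277% ± 0.0113 in axillary libraries (n = 6 each). Mesenteric libraries stood above spleen and above axillary libraries with an exact permutation p of 0.005 each, the smallest possible. Neither difference passed over lists and pairs (adjusted p = 0.0675 for both, exact permutation). Myeloid markers took 0.0494% ± 0.0212 in spleen, 0.0511% ± 0.0174 in mesenteric and 0.0213% ± 0.00822 in axillary libraries (n = 6 each; mesenteric against axillary adjusted p = 0.0675, exact permutation), and B cell markers 0.0313% ± 0.011, 0.0225% ± 0.0049 and 0.0155% ± 0.00794 (spleen against axillary adjusted p = 0.135, exact permutation). In these tests 0 of 18 lists passed for any pair of organs. The myeloid difference between mesenteric and axillary libraries also had the smallest possible p, 0.005. After adjustment a list could pass only if more tests had shared that p. The lack of passing lists therefore does not show that list shares were alike between organs.

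Organs differed in whole profiles. Libraries of the same organ shared more regions than libraries of different organs, with a difference in Jaccard index of 0.0615 between mesenteric and axillary, 0.038 between spleen and mesenteric and 0.0207 between spleen and axillary nodes (adjusted one-sided exact permutation p = 0.01 for each). High and low libraries differed by 0.0258 (0.699 within and 0.673 between levels, one-sided exact permutation p = 0.001). At equal list length these differences were 0.0159, 0.0162 and 0.015 between organs and 0.00927 between levels, with the same p-values. Mesenteric libraries held 20195 ± 3123 peaks, spleen 17165 ± 1325 and axillary 15045 ± 640 (n = 6 each). Axillary counts lay below mesenteric by 5150 and below spleen by 2120 (adjusted exact permutation p = 0.015 for both), and spleen minus mesenteric was -3030 (adjusted p = 0.05, not below the threshold). At equal depth, spleen minus axillary was 533 (adjusted p = 0.09) and spleen minus mesenteric -2080 (adjusted p = 0.0075, exact permutation). Among short-fragment libraries alone, spleen minus mesenteric was -2484 (permutation p = 0.1). The axillary libraries are mostly long-fragment ones, so the fragment estimate and that organ are largely confounded. The labels do not say whether the fragment estimate marks a batch. The share of summits near gene ends was 48.4% ± 0.945 in axillary, 46.6% ± 2.04 in spleen and 42.8% ± 4.14 in mesenteric libraries (n = 6; mesenteric minus axillary -5.57 percentage points, adjusted exact permutation p = 0.015), and at equal list length mesenteric minus axillary was 1.47 in the opposite direction (adjusted exact permutation p = 0.0075).

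Recovered reads, a comparison added after the data were examined, separated high from low cells at regions open in every library. Of 8428 regions, 118 rose and 64 fell in high cells (exact permutation, Benjamini-Hochberg), and 62 rose and 32 fell when reads were scaled to the genome background instead. Outside the Nr4a1 block and chromosome 14, 64 rose and 63 fell. Outside the Nr4a1 block these included rises near Fos (0.31 ± 0.06 log2, SE), Egr3 (0.33 ± 0.04), Dusp2 (0.24 ± 0.04) and Tnfsf11 (0.54 ± 0.08), and falls at Cblb (-0.18 ± 0.03) and Klf6 (-0.14 ± 0.02), each over 9 high and 9 low libraries. Chromosome 14, which carries Egr3, Elf1, Tnfsf11, Gzmb, Siah3, Serp2, Zmiz1, Tnfrsf19, Ccdc66 and Camk2g, stood 0.14 log2 higher in high libraries at the median of its 358 regions (exact permutation p = 0.00025, adjusted p = 0.00125 over 20 chromosomes), and held 43 of the 118 rises. In all, 10 of 20 chromosomes passed this test, with chromosome 11 next in size at 0.06 log2. Chromosome 14 also differed between organs, by 0.11 log2 for spleen minus mesenteric, 0.07 for spleen minus axillary and -0.05 for mesenteric minus axillary nodes (adjusted exact permutation p = 0.005 for each). Values of other chromosomes between organs are not given here, so these differences cannot be called particular to chromosome 14.

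**Figure D4:**
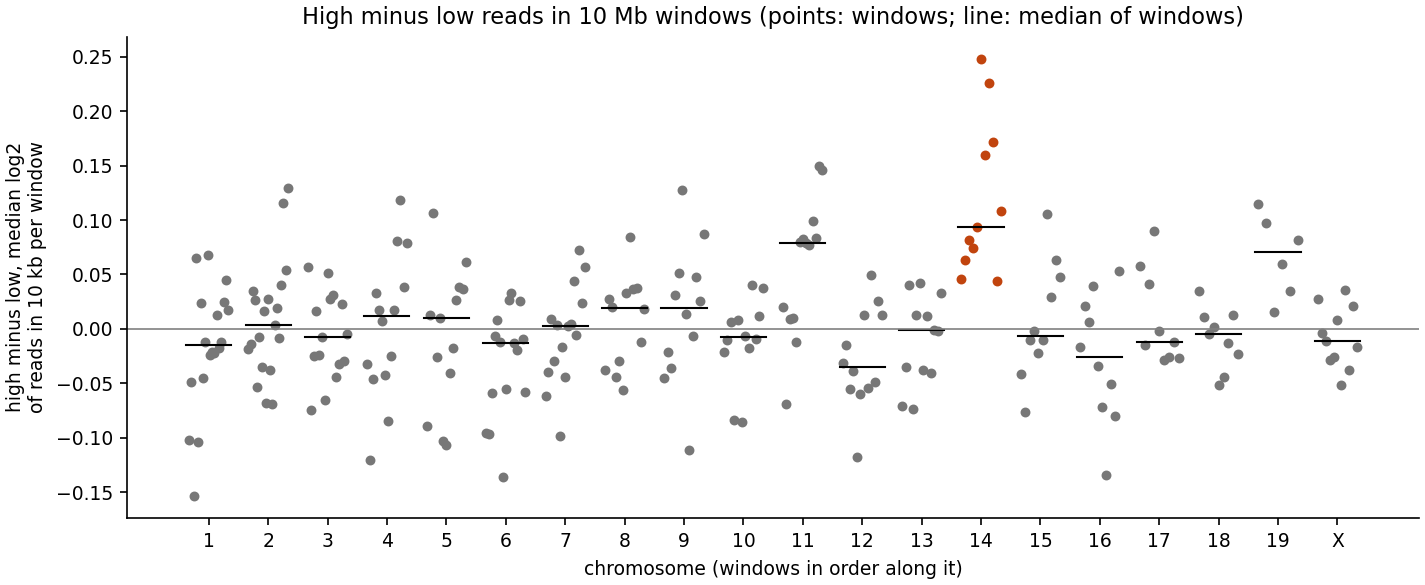
Median high minus low log2 reads in 10 Mb windows (points) of each chromosome in order, with a line at the median of its windows. On chromosome 14, 4 windows (up to 0.25) lie above the highest window of any other chromosome (0.15).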

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

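Regions near 13 genes had a peak in 3 of 3 high and 0 of 3 low libraries of one organ and the reverse in another, where 6.48 would arise if organs were independent, and this difference was not tested. A region outside Arid1b was present in the high libraries of spleen and the low libraries of mesenteric nodes. Regions near Shld1, Smpdl3b, Foxj2, Prr12, Camk4, a calcium-dependent kinase gene of T cells, Trim36 and Hsd17b4 were present in mesenteric high and spleen low libraries. A region inside Prdm1, which encodes the repressor Blimp-1, was present in axillary high and spleen low libraries, and regions near Trim71, Pde4d, Trappc8 and Arhgef6 in mesenteric high and axillary low libraries.

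Outside the chromosomes used, the lists held 125 peaks on the mitochondrial genome, 6 to 8 per library. High libraries had 7.22 and low libraries 6.67 on average (exact permutation p = 0.086, n = 9 each), and no pair of organs passed (smallest adjusted p = 0.18, exact permutation). The lists also held 279 peaks on other sequences, of which 40 lay on chromosome Y, 2 to 3 per library, and these were not analysed here.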

How the results depend on the processing

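The tests of equal depth, of 1 value per group, of short-fragment libraries alone, without mesenteric libraries, without chromosome 14 and the Nr4a1 block, with organ and level means removed, of recovered reads and of list calls in other settings were chosen only after the result was seen; the others were fixed earlier. The higher peak number of high libraries kept its direction and passed in every planned setting and with any library left out (2123 to 2706 peaks, largest exact permutation p = 0.0145). With 1 value per group, the differences of 2487 peaks and of -3.16 percentage points near gene ends had an exact p of 0.25, which is the smallest that design allows. No setting tested gave a called region in presence of peaks over all regions, so the counts below are unadjusted. Except where the construction of a setting shows it, the cause of a change was not tested.

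With only peaks of −log10 p of at least 10, 219 regions were more frequent in high libraries, 133 spleen and 111 axillary regions had 3 of 3 high and 0 of 3 low, and spleen minus mesenteric was -2607 peaks (adjusted p = 0.03, exact permutation). Regions near Sntb2 and Maml2 turned direction there (22.2 and 11.1 percentage points more high than low libraries). At equal list length, which removes differences in list length by construction, 80 regions were more frequent in high and 83 in low libraries and 357 differed between organs. Within organs there were 107 regions with peaks only in high spleen libraries, 170 and 129 in mesenteric (high and low) and 117 and 113 in axillary libraries, and 0 lists passed. Of the 9 calls made over a list alone, 0 were kept there or at equal depth, while regions of Cd69 and Crtam (between organs) and Tal1 (high against low) passed at equal list length and of Irf8 (between organs) at equal depth. The share near gene ends then differed by 0.0317 points for high minus low, by -0.0313 for spleen minus mesenteric, by 1.43 for spleen minus axillary and by 1.47 for mesenteric minus axillary nodes (the last pair of adjusted p-values 0.0075 each, exact permutation). When a peak had to cover 50% of a region, 23 regions were more frequent in low libraries, 229 spleen and 112 axillary regions had peaks in all low and no high libraries, and Lmna turned direction (-8.33 points). With no filter on regions, 24 were more frequent in low libraries. In total length covered, spleen minus axillary was 0.206 Mb (exact permutation p = 0.245).

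At equal depth, 198 regions were more frequent in high and 30 in low libraries, 508 differed between organs, 466 and 52 mesenteric regions were exclusive to high and low libraries, and 0 lists passed. Spleen minus mesenteric was -2080 peaks (adjusted p = 0.0075, exact permutation) and spleen minus axillary 533 (adjusted p = 0.09). The share near gene ends was 0.174 points for spleen minus axillary (adjusted p = 0.805, exact permutation) and -2.85 for mesenteric minus axillary (adjusted p = 0.06), and the high against low difference in spleen minus that in axillary nodes was -276.9 peaks (adjusted p = 0.69, exact permutation). The planned test of that difference between organs lost power where the organs' own difference was large, as it also carried that difference. With organ and level means removed, spleen minus mesenteric was -4758 peaks and mesenteric minus axillary 4872.7 (adjusted p = 0.0075 each, permutation). At equal depth they were -2449.6 and 2172.8 (adjusted p = 0.0075 each, permutation), with -276.9 for spleen minus axillary (adjusted p = 0.605). Short-fragment spleen and mesenteric libraries alone gave 98 regions for high and 0 for low, and the other organs without mesenteric libraries 27 and 8. Recovered reads gave 182 calls after adjustment, and 94 when scaled to the genome background.

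With the replicate block, which pairs libraries that share a number in the titles, 159 regions were more frequent in high and 4 in low libraries, against 335 and 15 without it, and 0 lists passed. Mesenteric minus axillary was -5.57 points near gene ends (adjusted p = 0.0938, exact permutation), and the similarity differences of 0.038, 0.0207 and 0.0615 had an adjusted exact p of 0.0625, because the block allows fewer relabellings. High and low libraries of the same number correlated at -0.00453 to 0.00714 and those of different numbers at -0.0104 to 0.01. As libraries of a group differed by no more than counting noise, these correlations could not show whether equal numbers mark pairs.

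Leaving out 1 library changes the steps of the exact tests by construction, and gave 363 to 621 regions for high, 20 to 40 for low and 1032 to 1439 between organs, with 0 or 1 list passing. Spleen minus mesenteric ranged from -3358 to -2484 peaks and passed without spleen low replicate 1 (-3358 peaks, adjusted p = 0.02, exact permutation) or 2 (-3247, adjusted p = 0.035). Without spleen low replicate 3, the shallowest spleen library, the share near gene ends differed between spleen and axillary nodes (-2.69 points, adjusted p = 0.0075, exact permutation; -1.29 at the other end, without spleen low 1) and the high against low difference in spleen lay below that in mesenteric nodes (-5849 peaks, adjusted p = 0.015, against -4102 without spleen low 1). The spleen minus axillary value of that difference ranged up to 771 and turned to -976 there, and to -48.2, -115 and -225 without spleen high 3, axillary low 1 and axillary high 3. The similarity difference of spleen against mesenteric libraries ranged from 0.0332 to 0.0436 and was 0.0348, 0.0347 and 0.0352 without mesenteric low 1, 2 and 3, each with an adjusted exact p of 0.05, the smallest possible there.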

Other observations

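The tests on recovered reads, on the Nr4a1 block, on chromosome 14, on the mesenteric libraries and on splits within an organ were chosen only after the result was seen; the splits of all libraries for presence of peaks were fixed earlier. At regions open in all libraries, reads in high cells rose near Anxa3 (0.65 ± 0.13 log2, SE), Mef2c (0.59 ± 0.17), Plxnc1 (0.53 ± 0.05), Ets2 (0.52 ± 0.10), Hivep3 (0.49 ± 0.08), Elf1 on chromosome 14 (0.39 ± 0.06) and Tnfrsf1b, a TNF receptor gene (0.26 ± 0.06). Reads fell near Gabra4 (-0.46 ± 0.06), at Nab1, which encodes a corepressor of Egr proteins (-0.25 ± 0.04), at Ppp3ca, a calcineurin subunit gene (-0.22 ± 0.03), at Gsk3b (-0.15 ± 0.02) and at Zbtb20 (-0.14 ± 0.03), each over 9 high and 9 low libraries. As a list, AP-1, NFAT, NF-kB and IRF factors rose by 0.09 log2 over 21 regions (adjusted p = 0.0055, exact permutation), with Fos as the called member, while its share of peak regions was lower in high libraries without passing (0.332% against 0.35%, adjusted p = 0.301, exact permutation). The TCR signal list without the Nr4a1 block did not pass (-0.0027 over 36 regions, exact permutation p = 0.911), although Dusp2 and Egr3 rose in it and 4 Nr4a1 regions of the block, left out of the mean, rose by 0.67 to 0.91 log2, and none of the other 9 lists did. Over 100 splits of the libraries the real split was the 1 with as many calls (182, highest other 0), so chance can be excluded for the grouping of these libraries, but not for differences between animals or preparations, which were not measured.

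Between organs the same reads placed lists apart. Retinoic acid and TGF-beta regions stood higher in mesenteric than in axillary nodes (0.17 log2 over 12 regions, adjusted p = 0.015, exact permutation) and than in spleen (spleen minus mesenteric -0.11, adjusted p = 0.0381). TCR signal regions stood lower in spleen and mesenteric than in axillary nodes (-0.13 and -0.12 over 36 regions, adjusted p = 0.015 for both, exact permutation), and negative regulators likewise (-0.14 and -0.12). Most lists stood lower in spleen than in axillary nodes, also the naive (-0.115), homing (-0.11) and regulatory T cell lists (-0.09, adjusted p = 0.015 for each, exact permutation) and T helper lineages (-0.09, adjusted p = 0.044). Interferon response regions stood higher in spleen than in axillary nodes (0.11 over 14 regions, adjusted p = 0.015, exact permutation). The housekeeping list also differed, mesenteric minus axillary by 0.10 and spleen minus mesenteric by -0.07 (adjusted p = 0.015 for both, exact permutation), so differences of this size are not specific to T cell lists. Axillary libraries were also mostly long-fragment ones and had the lowest mean depth, which these tests cannot separate from the organ. No single region was called between organs by the exact permutation test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.0761). Unadjusted, 1045 and 836 regions passed for spleen minus axillary. With 400 relabellings no p can fall below 0.005, so a region could pass only if many tests shared that smallest p. The lack of calls therefore does not show that single regions were alike between organs.

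The block around Nr4a1 had more reads in high cells. Greater depth was excluded as the cause, since the lowest ratio of a block region was 1.497 (at Atg101), above the upper bound of the central 95% of other regions, 1.22. Low libraries also stood far above background over the block (42.55 times), and the lowest region of any other run of 22 regions reached at most 4.81 times. Extra copies of the locus in all libraries, for example through a reporter transgene that carries Nr4a1 flanks, may underlie this and were not tested. The difference between high and low cells may reflect more copies in high cells or more open copies. Extra copies of the whole block, as open as the rest, would give all regions 1 ratio and leave fold over local background unchanged. The ratios ran from 1.497 to 1.995, a spread of 0.4141 log2 (SE 0.0581). Fold also ran lower in high libraries at the shared Nr4a1 regions. These values would argue against equal copies of the whole block as the only cause only if reads followed copy number in proportion. Duplicate handling is not given, so that is not known at such high read numbers, and equal copies cannot be excluded. Copies of parts of the block and more open copies cannot be told apart, as both allow any ratio above 1. The labels give the genotype as WT and do not give a copy number of the reporter. Sequencing of tail DNA and of genomic DNA of both sorted fractions would give the copy number over the block, and single-copy presence would leave opening.

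Chromosome 14 also had more reads in high cells. A trend with region strength was excluded as the whole cause, as the difference to matched regions was 0.1469 (exact permutation p = 0.00025), although weaker regions of the chromosome differed more than stronger ones (0.1801 against 0.1045, permutation p = 0.0001). Copies of the whole chromosome stay open: its 10 Mb windows differed by 0.204 log2, more than shuffled regions (permutation p = 0.0083) but less than those of 5 other chromosomes (up to 0.239). Accessibility of part of the chromosome or copies of part of it could each underlie the highest window, 0.2484 at 50 to 60 Mb, and these explanations cannot be told apart. Genomic DNA of the sorted fractions would part them, and mapping of the reporter insertion would show whether it lies there, which was not tested.

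Mesenteric high libraries had the most peaks. Depth was excluded as the whole cause, as 2789.4 of 5697 peaks remained at equal depth, beyond the largest range within a group (1424), with fragment estimates of 163 bp in high and 162 to 172 bp in low libraries. Higher enrichment at shared regions was not seen. Summit reads over background were 125.9 in high and 132.5 in low libraries (high minus low -6.6), the opposite of what it predicts. The libraries overlapped (exact permutation p = 0.2), so the values do not exclude it. Separate handling of these 3 libraries or a state of the cells may also underlie the rest and cannot be told apart, as libraries of this group differed by no more than counting noise (highest chi-square per summit among them 0.8452). Libraries from separately housed animals, prepared in mixed batches, would part them.

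For presence of peaks, 1 of 100 splits, the real one, gave as many regions for high against low (350, highest other 264), 1 of 100 at equal list length (163, highest other 121) and 1 of 100 between organs (851, highest other 487), so chance can be excluded for the grouping of these libraries only. Within an organ, 10 splits are too few for a share under 0.05. The real split was 1 of 10 in spleen (301, highest other 225), 1 of 10 in mesenteric (1058, highest other 200) and 1 of 10 in axillary nodes (260, highest other 186).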
